A study of Homo sapiens with 8 samples.

How the data were processed

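Total RNA from 8 BT549 cultures, 4 attached and 4 in forced suspension, was hybridised to arrays that measure whole transcripts with several probes per probe set. Per the labels' protocols, cells were kept in medium with 10% serum and insulin, RNA was extracted with TRIzol, and 1 µg per sample was labelled with biotin. The labelling kit named in the labels is one used for small-RNA arrays, whereas the values analysed here are those of a gene-level array, so how the RNA was labelled for these arrays stays uncertain. The labels also disagree on how long attached cells were cultured: 24 h in the growth field and 48 h in the treatment field, against 24 h in both for suspended cells.

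The values are log2 signals that the authors deposited in 1 table of 33297 probe sets by 8 arrays. That they are on the log2 scale was inferred from their size, with array maxima of 13.69 to 13.73, since no header or label states it. Per the submitters' processing notes, Partek was used. Its version, the background correction, the normalization and the summarisation are not given in the sources used here. Array medians lay between 6.02 and 6.07, 25th percentiles between 4.70 and 4.75 and 75th percentiles between 7.50 and 7.55, and no further normalization was applied for the main results. No detection call or background measure was used here, so low signals carry no statement of presence. The 25th percentile of gene means, 5.28, serves as a reference for low signal.

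Probe sets were named from the platform annotation supplied with the table. Of the 33297 probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 (36.3%) had none there, and only those with 1 symbol were tested as genes. Symbols were checked against the RefSeq gene table of assembly GRCh38.p14 through the gene ID: 19429 matched, 31 did not, and 0 symbols needed an update. For 769 genes with more than 1 probe set, the probe set with the highest mean over all 8 arrays stood for the gene, and for 1 of them different probe sets were called in opposite directions. This left 18417 genes. Positions are not given, since the table holds none.

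Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with p-values adjusted by the Benjamini-Hochberg method and a threshold of 0.05. A 2-fold change is an absolute log2 difference of at least 1. Differences are suspended minus attached, SE is the moderated standard error from limma, and SD is over the 4 arrays of a group. Since the samples are biological replicates of a single cell line, p-values speak to these cultures and not to other lines. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

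Gene lists were fixed before the data were examined, 35 in all: kynurenine pathway, aryl hydrocarbon receptor targets, NF-kB targets, interferon-stimulated genes, G1/S and replication, G2/M and mitosis, YAP targets, SRF and actin, integrins and adhesion, extracellular matrix, proteases, TGF-beta targets, cholesterol synthesis, fatty acid synthesis, hypoxia, glycolysis, oxidative phosphorylation, the ATF4 response, the unfolded protein response, heat shock, NRF2 targets, p53 targets, the BCL2 family, autophagy, immediate-early genes, mesenchymal, epithelial, luminal breast and basal breast genes, stem cell markers, leukocyte, endothelial and adipocyte markers, ribosomal proteins and short-lived RNAs. They held 570 entries, of which 529 had a tested gene and 41 are not analysed here. Some genes belong to more than 1 list. Each list was tested with limma's camera at its preset correlation of 0.01, which compares a list with the remaining genes, and beside it with camera at a correlation estimated from the data and with fry, which does not compare a list with other genes. The members past the threshold were counted with p adjusted over all 18417 genes and adjusted over the list alone.

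The genes named in the text follow a rule also fixed before the data were examined: the 15 largest rises and 15 largest falls among called genes whose groups do not overlap, the 4 members of each list with the smallest adjusted p, further members where a count of 5 or fewer is given, every measured member of the kynurenine list, and AHR. This gave 204 genes, 175 of them past the threshold. The uncalled and unmeasured aryl hydrocarbon receptor targets are named besides, outside this rule.

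The pipeline was tested on simulated data with the 18417 genes and 4 arrays per group. It recovered 57% of 100 genes changed 1.25-fold and 98% of 100 genes changed 2-fold, with 7 unchanged genes called (4.32% of calls). Only these genes were changed, whereas 20.6% of tested genes were called in the data. The adjusted threshold depends on that share, so these recovery rates need not hold for the data. The shifted list was called and 0 of 34 lists left alone were, by camera at its preset correlation. With an estimated correlation the shifted list was called as well. Each gene was simulated independently of the others, so this says nothing of how often lists of correlated genes are called falsely. Alternatives tried were the replicate number as a block, quantile normalization, centring of each array on its median, only genes above the median or the 25th percentile of mean level, an intensity trend in eBayes, array weights, the mean of a gene's probe sets, all probe sets, and leaving out each array in turn. All 35 ways to divide the 8 arrays into 4 and 4 were also fitted.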

Results

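BT549, a human breast cancer cell line of the triple-negative type, was profiled on 8 gene expression arrays, 4 per condition. In one condition the cells grew attached to ordinary culture plastic; in the other they were kept from attaching on plates coated with poly-HEMA, a polymer to which cells do not stick. The series describes the 4 samples of each condition as biological replicates. Suspended cultures lasted 24 h, and the labels give the attached cultures both as 24 h and as 48 h, so culture time cannot be told apart from attachment if the longer time holds. The comparison asks which transcripts differ when these cells are kept from attaching. Log2 signals over 33297 probe sets had array medians between 6.02 and 6.07 and array maxima between 13.69 and 13.73. Arrays have no read depth, and their number, 4 against 4, limits the precision. Across the 33297 probe sets, arrays correlated at r = 0.995 to 0.996 among attached and 0.993 to 0.996 among suspended samples. Between the groups r was 0.987 to 0.994, and 0 pairs of arrays were identical. The first principal component, over the 18417 tested genes, held 56.5% of the variance. It placed the attached arrays at −15.2 to −10.7 and the suspended arrays at 10.1 to 17.5.

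TDO2 signal was 6.19-fold higher in suspended than in attached BT549 cells. The log2 difference was 2.63 (SE 0.059, n = 4 per group, limma adjusted p = 1.02e-09). TDO2 encodes the enzyme that opens the ring of tryptophan in the first step of the kynurenine pathway. Without a background measure, fold values here are ratios of signals and not of transcript amounts. The TDO2 signal (probe set 8097991) was 5.59 ± 0.04 attached and 8.22 ± 0.11 suspended (mean log2 ± SD). TNFRSF11B, the decoy receptor osteoprotegerin, rose 4.19-fold, CHI3L1, a secreted chitinase-like glycoprotein, 3.97-fold, and the Notch ligand JAG1 3.42-fold. CCN1, a matrix-associated protein and known YAP target, was 3.80-fold lower (probe set 7902687, log2 difference −1.93, SE 0.062, adjusted p = 1.48e-08). NCEH1, a cholesteryl ester hydrolase, was 3.30-fold lower, and TGM2, the protein-crosslinking tissue transglutaminase, 2.97-fold lower.

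Of 18417 genes tested, 3787 (20.6%) passed adjusted p under 0.05 by limma, 1910 higher and 1877 lower in suspension. At least a 2-fold change was met by 63 of them, 43 higher and 20 lower; the median absolute log2 difference of the called genes was 0.28. The 4 suspended and 4 attached values did not overlap for 4575 genes (24.8%), against 2.86% by chance. The balance of directions depended on scaling: 50.4% of calls were higher as deposited and 35.2% after each array was centred on its median (1340 higher, 2472 lower). Besides TDO2, TNFRSF11B, CHI3L1 and JAG1, the 15 largest rises among genes with non-overlapping groups were, in log2, SCG2 (1.81), KYNU (1.48), SECTM1 (1.45), the prostaglandin E synthase PTGES (1.45), SEL1L3 (1.44), the secreted glycoprotein STC1 (1.44), CYP1B1 (1.42), SNED1 (1.39), SCARA5 (1.34), DOCK11 (1.30) and the carbonic anhydrase CA12 (1.28). Besides CCN1, NCEH1 and TGM2, the 15 largest falls were the actin-binding TAGLN (−1.31), the growth factor carrier IGFBP3 (−1.30), MARCHF4 (−1.26), CRIM1 (−1.24), DDAH1 (−1.23), the DNA repair helicase ERCC2 (−1.19), PLAC8 (−1.18), the surface glycoprotein THY1 (−1.14), PDCD1LG2, which encodes the immune checkpoint ligand PD-L2 (−1.13), the adhesion receptor ADGRG1 (−1.13), the TWEAK receptor TNFRSF12A (−1.11) and CCDC80 (−1.08). For these 30 genes the SE lay between 0.046 (CCDC80) and 0.101 (CHI3L1), and the adjusted p was at most 1.05e-06 (TNFRSF12A). The attached mean of SEL1L3, 5.108, lies below the 25th percentile of all gene means (5.28), where the size of a rise is less certain for lack of a background measure.

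**Figure D1:**
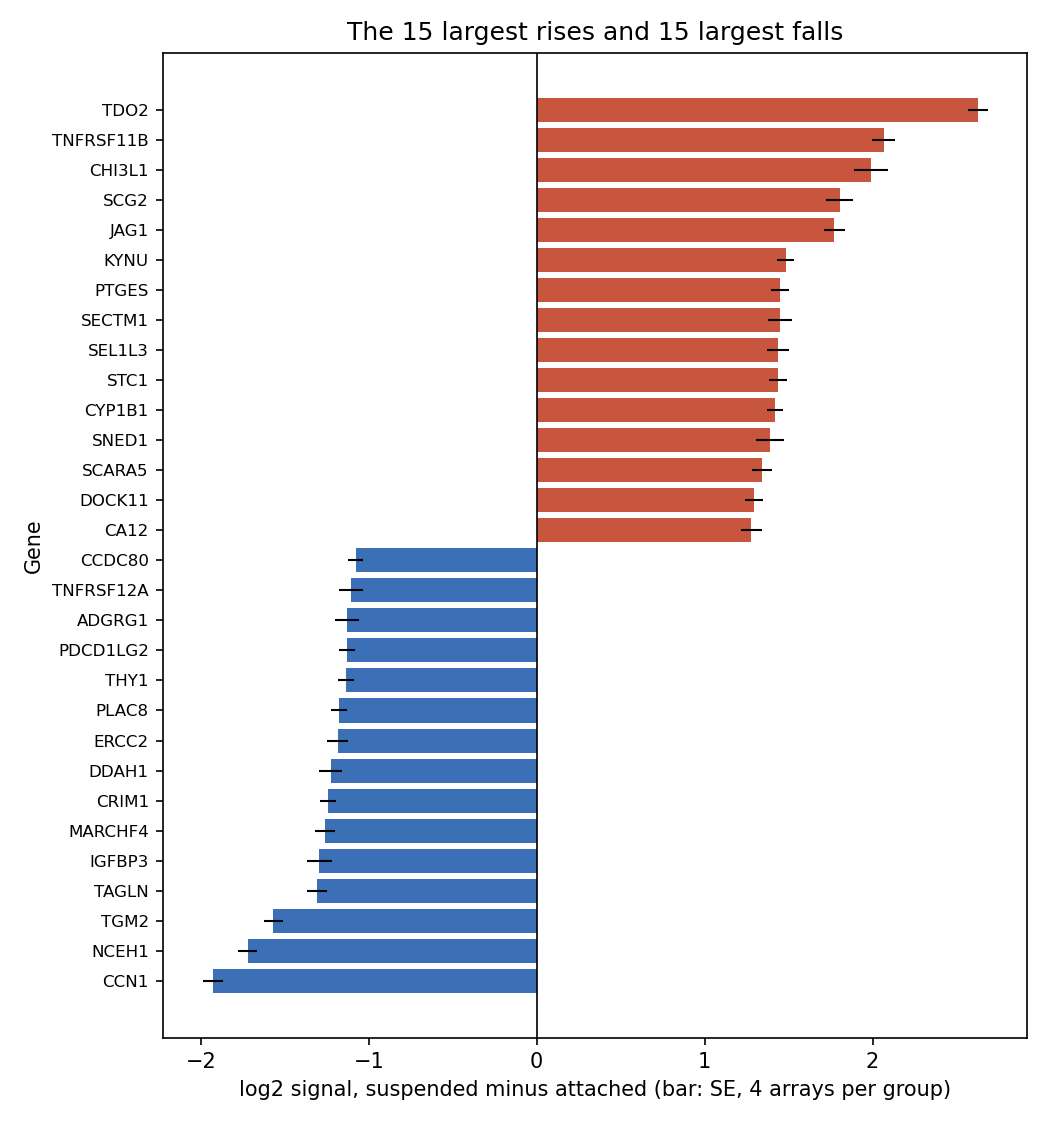
Log2 difference, suspended minus attached, of the 15 genes with the largest rise and the 15 with the largest fall (bars, 4 arrays per group; lines, standard error from limma). TDO2 leads the rises at 2.63 and CCN1 the falls at −1.93.

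Within tryptophan breakdown through kynurenine, the rises centred on TDO2 and on KYNU, the kynureninase, which went from 7.47 ± 0.06 to 8.96 ± 0.06 (mean log2 ± SD, n = 4 per group; 2.79-fold). Of 12 measured members 5 rose and 0 fell, and with p adjusted over the list alone 5 rose and 1 (IDO2) fell, as also at unadjusted p. The other rises were small: IDO1 (0.21), KYAT3 (0.22) and QPRT (0.19). With 1 array left out in turn, IDO1 was no longer called without attached replicate 1 or 3 or suspended replicate 1 (0.16 to 0.23 over the 8 refits), KYAT3 when any array other than suspended replicate 1 was left out (0.18 to 0.29), and QPRT without attached replicate 2, 3 or 4 or suspended replicate 1 or 4 (0.16 to 0.22). Not past the test were IDO2 (−0.13), HAAO (0.10), AFMID (0.07), KYAT1 (−0.04), AADAT (−0.03), KMO (0.02) and ACMSD (0.00). IDO1, IDO2, KMO and ACMSD had mean signals below 5.28, the 25th percentile of all genes. The list ranked above other genes by limma's camera (adjusted p = 0.0284, and adjusted p = 0.184 with an estimated correlation), and without suspended replicate 1 this call was lost (adjusted p = 0.0622).

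AHR, the aryl hydrocarbon receptor, which kynurenine is known to activate, was 2.16-fold higher in suspension (log2 1.11, SE 0.048, adjusted p = 6.24e-08; probe set 8131614). Of 9 measured receptor targets 4 rose and 1 fell, with the same counts when adjusted over the list alone. The 4 not past the test were CYP1A1, CYP1A2, ALDH3A1 and STC2, while AHRR and UGT1A6 had no tested gene. CYP1B1, a monooxygenase, rose 2.68-fold, followed by the quinone reductase NQO1 (0.90), NFE2L2 (0.42) and TIPARP (0.42), while the amino acid transporter SLC7A5 fell (−0.36). Camera called the list higher (adjusted p = 0.0169, and adjusted p = 0.233 with an estimated correlation). Of 22 measured NF-kB targets 3 rose, namely ICAM1 (0.53), SOD2 (0.42) and LIF (0.27), and 2 fell, CXCL2 (−0.24) and NFKB1 (−0.25); adjusted over the list alone the counts were also 3 and 2, and camera did not call the list (adjusted p = 0.869). LIF, with an attached mean of 5.134, also below 5.28, was not called without attached replicate 1 or 3 (0.20 to 0.32 over the 8 refits), and NFKB1 when any array other than suspended replicate 2 was left out (−0.33 to −0.19). The kynurenine, receptor and NF-kB lists were drawn up knowing published work on this question, so their counts are not independent evidence of a direction.

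**Figure D2:**
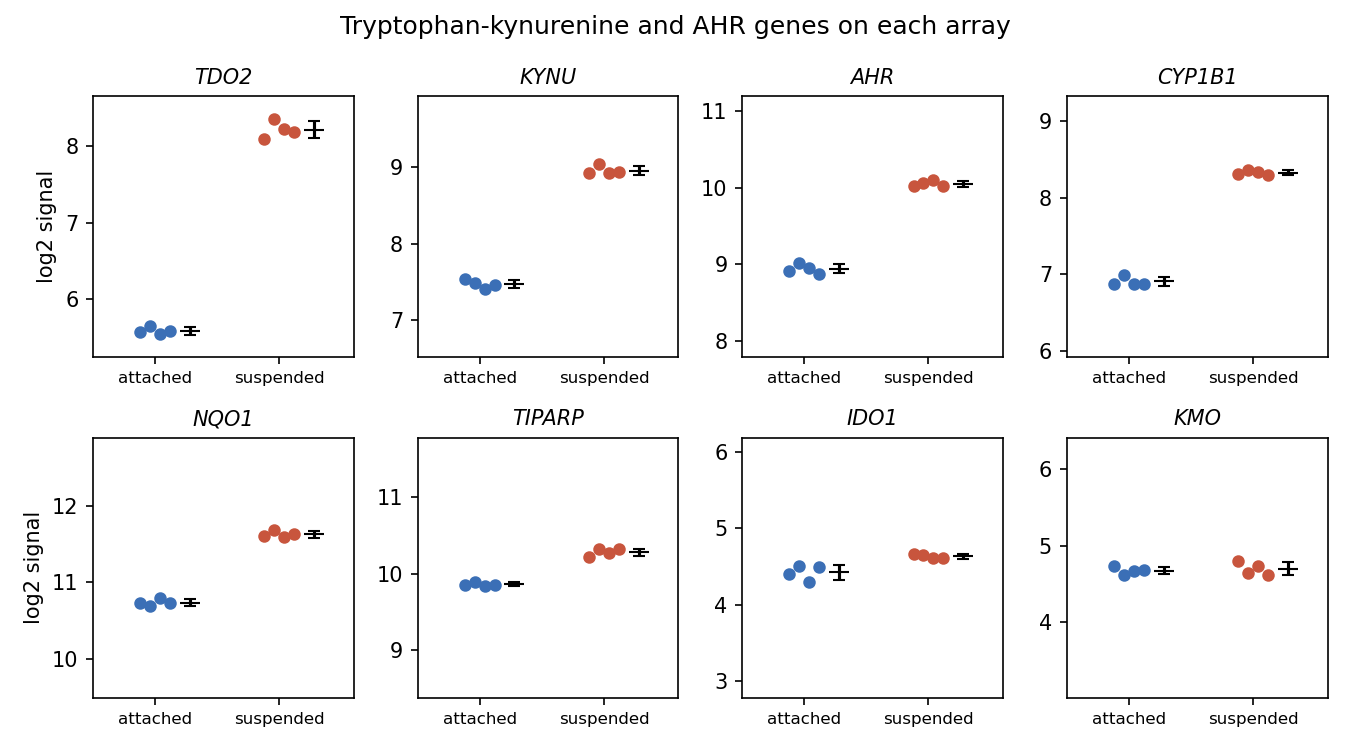
Log2 signal of 8 genes of the kynurenine pathway and the aryl hydrocarbon receptor response on each of the 4 attached and 4 suspended arrays (points), with the group mean ± SD at the side; every panel spans the same range of log2 units. TDO2, KYNU, AHR, CYP1B1, NQO1, TIPARP and IDO1 are higher on all 4 suspended arrays than on any attached array. The step of IDO1 is small and at low signal, with means of 4.43 attached and 4.64 suspended. KMO, at 4.67 ± 0.04 attached and 4.70 ± 0.08 suspended, is not separated in this way.

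Cell cycle transcripts were lower in suspension by small steps. Among 20 genes of G1/S transition and DNA replication 13 fell and 0 rose (14 and 0 adjusted over the list alone, 15 and 0 at unadjusted p), with the replication factors CDC6 (−0.51), CDC45 (−0.49) and GINS1 (−0.40) and the thymidylate synthase TYMS (−0.32) as examples. Among 22 G2/M and mitosis genes 19 fell and 0 rose (20 and 0 both adjusted over the list alone and at unadjusted p), including the mitotic kinases TTK (−0.39) and BUB1B (−0.31), HMMR (−0.33) and cyclin CCNA2 (−0.32). Median log2 differences were −0.19 and −0.25. Camera called both lists lower (adjusted p = 1.98e-07 and 3.88e-11; adjusted p = 0.184 for each with an estimated correlation).

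Among genes tied to cell spreading and contractility more fell than rose. Of 17 YAP targets 11 fell and 2 rose, also when adjusted over the list alone; CCN1, CRIM1 and the receptor kinase AXL (−1.04) fell furthest among those named, and TGFB2 (0.72) and the ectonucleotidase NT5E (0.34) went the other way. Of 17 SRF and actin cytoskeleton genes 9 fell and 1 rose, again with the same counts adjusted over the list alone. TAGLN, CALD1 (−0.97), TPM1 (−0.83) and FHL2 (−0.29), which bind actin or act in its signalling, fell, and LMOD1 rose (0.29), a call lost without attached replicate 3 (0.21 to 0.32 over the 8 refits). Camera called both lists lower (adjusted p = 3.20e-06 for YAP targets and 1.59e-05 for SRF and actin genes; adjusted p = 0.184 for each with an estimated correlation).

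Integrin and adhesion genes moved in both directions. Of 21 measured, 5 rose: the integrin subunits ITGA2 (1.28), ITGB8 (1.10), ITGA6 (0.72) and ITGB4 (0.35), and the focal adhesion kinase PTK2 (0.35). TNS3 (−0.43) was among 7 that fell; adjusted over the list alone 5 rose and 8 fell, and camera gave adjusted p = 0.860. Of 22 extracellular matrix genes 8 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.104), with COL3A1 (0.65), FBN1 (0.52) and COL4A1 (0.50) among the rises, and the crosslinking enzyme LOX (−0.88), THBS1 (−0.46) and COL12A1 (−0.28) as the falls. Of 17 matrix-degrading proteases and their regulators 4 rose, CTSL (0.85), PLAT (0.59), MMP14 (0.27) and MMP2 (0.24), and 2 fell, MMP9 (−0.58) and MMP1 (−0.22), the same adjusted over the list alone (camera adjusted p = 0.789). MMP2 lost its call without attached replicate 1 or 3 (0.20 to 0.27 over the 8 refits) and MMP1 without attached replicate 1, 2 or 3 or suspended replicate 1 or 4 (−0.27 to −0.18). Of 13 TGF-beta targets 6 rose, among them INHBA (0.49) and ID3 (0.45), and 3 fell, LTBP2 (−0.92), TGFBI (−0.66) and SKIL (−0.28); adjusted over the list alone 6 rose and 4 fell (camera adjusted p = 0.353).

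Immediate-early and growth factor feedback genes rose in part. Of 19 measured 9 rose, and 4 fell (11 and 4 adjusted over the list alone). The rises included the feedback regulators SPRY4 (0.86), SPRY2 (0.70), PHLDA1 (0.63) and DUSP4 (0.60), and the falls were the transcription factor genes FOSL1 (−0.43), FOSB (−0.40), MYC (−0.40) and JUN (−0.32). Camera called the list higher (adjusted p = 0.0389, and adjusted p = 0.746 with an estimated correlation), a call lost without attached replicate 1 or 4 or suspended replicate 2 or 4 (adjusted p up to 0.108), with replicate number as a block (0.0653) with array weights (0.0609) and when only genes above the median or the 25th percentile level were kept (0.0588 and 0.0679). Among 13 genes of short-lived RNAs, 5 rose, BTG1 (0.52), ID1 (0.41), JUNB (0.39), SGK1 (0.35) and IER3 (0.32), and 2 fell, MYC and KLF6 (−0.18), the same adjusted over the list alone (camera adjusted p = 0.353). With 1 array left out in turn, KLF6 kept its call only without attached replicate 1 or suspended replicate 2 (−0.21 to −0.15 over the 8 refits).

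Genes of the amino acid response driven by ATF4 were lower on balance. Of 17 measured 10 fell, such as the serine synthesis enzyme PSAT1 (−0.65) and the folate enzyme MTHFD2 (−0.45), while DDIT4 (0.62), CEBPB (0.48) and ATF3 (0.25) rose; adjusted over the list alone 12 fell and 3 rose. With 1 array left out in turn, ATF3 kept its call only without suspended replicate 2 or 3 (0.17 to 0.29 over the 8 refits), and with all 8 arrays it lost the call with the replicate number as a block, quantile normalization or median centring (adjusted p = 0.0986, 0.0969 and 0.0811). Camera called the list lower (adjusted p = 0.00212, and adjusted p = 0.184 with an estimated correlation). Of 10 heat shock genes 5 fell, HSP90AB1 (−0.29), HSPD1 (−0.29), DNAJA1 (−0.19), DNAJB1 (−0.18) and HSPH1 (−0.17), and the co-chaperone BAG3 rose (0.45); adjusted over the list alone 7 fell and 1 rose. DNAJA1 lost its call when any array other than suspended replicate 3 was left out (−0.23 to −0.14), HSPH1 when any array other than attached replicate 3 or suspended replicate 2 was left out (−0.21 to −0.14), and DNAJB1 without attached replicate 4 (−0.20 to −0.16). Camera called the heat shock list lower (adjusted p = 0.0178, and adjusted p = 0.249 with an estimated correlation), and did not after a further quantile normalization (adjusted p = 0.0886) or with only genes above the median level (0.0813).

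Of 15 genes of the unfolded protein response SEL1L (0.22) and DNAJB9 (0.16) rose and XBP1 fell (−0.31), 3 and 1 adjusted over the list alone, and camera gave adjusted p = 0.869. SEL1L lost its call when any array other than suspended replicate 4 was left out (0.18 to 0.27 over the 8 refits) and DNAJB9 when any of the 8 was left out (0.12 to 0.18). Of 13 NRF2 targets 5 rose, FTL (0.39), AKR1C1 (0.38), GCLC (0.34), OSGIN1 (0.24) and TXNRD1 (0.17), and 2 fell, the haem oxygenase HMOX1 (−0.33) and GCLM (−0.31); adjusted over the list alone 5 rose and 3 fell (camera adjusted p = 0.794). The AKR1C1 value is that of the brighter of its probe sets; the other differed by 0.05 (adjusted p = 0.768 over all probe sets), and with their mean AKR1C1 was not called (0.218, adjusted p = 0.0672). With 1 array left out in turn, TXNRD1 kept its call only without suspended replicate 1 (0.14 to 0.20). Of 13 p53 targets the cytokine GDF15 (0.91), TP53INP1 (0.56), the cell cycle inhibitor CDKN1A (0.41) and RRM2B (0.21) rose and PHLDA3 fell (−0.22), 4 and 2 adjusted over the list alone (camera adjusted p = 0.190). RRM2B was not called after each array was centred on its median (0.166, adjusted p = 0.0533). PHLDA3 lost its call without attached replicate 2 or 3 or suspended replicate 2 or 3 (−0.26 to −0.18).

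In the BCL2 family of cell death regulators, BCL2L11 (0.82), which encodes the pro-apoptotic BIM, and BMF (0.46) rose, while PMAIP1, which encodes NOXA (−0.44), and the anti-apoptotic BCL2 (−0.17) fell; these were the called members of 15, with 3 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.869). BCL2 was not called without attached replicate 1 or 3 or suspended replicate 4 (−0.19 to −0.15 over the 8 refits). Of 18 autophagy genes 7 rose, including WIPI1 (0.88), GABARAPL1 (0.63), NBR1 (0.43) and the lysosomal LAMP2 (0.36), and ATG5 fell (−0.17), a call kept only without attached replicate 1 or suspended replicate 1 among the 8 refits (−0.19 to −0.14). Adjusted over the list alone 8 rose and 1 fell. Camera called the autophagy list higher (adjusted p = 0.0157, and adjusted p = 0.184 with an estimated correlation).

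Genes of lipid and sugar metabolism moved in both directions. Of 18 cholesterol synthesis genes 3 rose, HMGCS1 (0.31), INSIG1 (0.24) and STARD4 (0.19), and 2 fell, DHCR7 (−0.34) and NSDHL (−0.14), with 4 and 5 adjusted over the list alone (camera adjusted p = 0.869). STARD4 was not called without attached replicate 3 (0.16 to 0.21 over the 8 refits), nor NSDHL when any array other than suspended replicate 3 was left out (−0.16 to −0.13). Of 11 fatty acid synthesis genes the desaturases FADS2 (0.45) and SCD (0.45) and the regulator SREBF1 (0.23) rose and ELOVL6 fell (−0.41), 4 and 1 adjusted over the list alone (camera adjusted p = 0.353); SREBF1 was not called with the replicate number as a block (0.225, adjusted p = 0.0521). Of 19 hypoxia genes 5 rose, ALDOC (0.42), NDRG1 (0.37), BNIP3L (0.28), EGLN3 (0.27) and ANKRD37 (0.18), and 4 fell, ANGPTL4 (−0.95), the glucose transporter SLC2A1 (−0.49), BNIP3 (−0.44) and ADM (−0.37), the same adjusted over the list alone (camera adjusted p = 0.869). ANKRD37 lost its call without attached replicate 1 or 4 or suspended replicate 1 or 4 (0.15 to 0.20). Of 12 glycolysis genes PFKP (−0.65), HK1 (−0.29) and GPI (−0.26) fell and the pyruvate kinase PKM rose (0.51), also adjusted over the list alone (camera adjusted p = 0.353).

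Of 17 genes of oxidative phosphorylation CYC1 fell (−0.27) and 0 rose, the same adjusted over the list alone, while at unadjusted p 3 fell and 1 rose. Camera called this list lower (adjusted p = 0.0488, and adjusted p = 0.184 with an estimated correlation), with a median log2 difference of −0.09. That call was lost without attached replicate 1, 2 or 3 or suspended replicate 1, 3 or 4 (adjusted p up to 0.0933), after quantile normalization (0.206), with array weights (0.0609) and when only genes above the median or the 25th percentile level were kept (0.255 and 0.0887). Of 17 cytosolic ribosomal protein genes 0 rose and 0 fell by limma, also adjusted over the list alone, and at unadjusted p 1 fell and 0 rose; camera gave adjusted p = 0.278, and RPL8 (−0.06) and RPS2 (−0.09) are examples. Of 18 interferon-stimulated genes IRF9 rose (0.26) and 0 fell, the same adjusted over the list alone, with 5 higher and 0 lower at unadjusted p (camera adjusted p = 0.163).

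SNAI2, which encodes the mesenchymal transcription factor SLUG, rose 2.35-fold (log2 1.23). Of 12 mesenchymal genes 6 rose, including TWIST2 (0.35) and ZEB1 (0.27), and N-cadherin, CDH2, fell (−0.38); adjusted over the list alone 8 rose and 1 fell. Camera called the list higher (adjusted p = 0.0284, and adjusted p = 0.200 with an estimated correlation), and did not without suspended replicate 2 (adjusted p = 0.0525). Of 16 epithelial genes 0 rose and 0 fell by limma, also adjusted over the list alone. At unadjusted p 1 was lower and 0 higher (camera adjusted p = 0.869). CDH3 differed by −0.15 and KRT19 by 0.18, with mean signals of 8.26 and 6.66. CLDN4 (4.885) and ST14 (5.15) had mean signals below 5.28, where the lack of a call says little. Of 11 stem cell markers 4 rose, the Notch targets HES1 (0.66) and HEY1 (0.65), SOX9 (0.37) and KLF4 (0.33), and 0 fell, the same adjusted over the list alone and at unadjusted p (camera adjusted p = 0.0912).

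Among 12 luminal breast genes GATA3 (0.49) and FOXA1 (0.18) rose and KRT7 (−0.50), MYB (−0.42) and XBP1 (−0.31) fell, and among 8 basal breast genes KRT15 (1.01) and CD44 (0.22) rose and EGFR (−0.45) and CAV1 (−0.16) fell; both lists gave the same counts adjusted over the list alone (camera adjusted p = 0.869 and 0.384). With 1 array left out in turn, FOXA1 kept its call only without suspended replicate 3 (0.13 to 0.21 over the 8 refits), and CAV1 was not called without attached replicate 2 or 3 or suspended replicate 1 (−0.17 to −0.14). Some markers of cell types other than breast cancer cells passed the test. Their counts are to be read against the 20.6% of all tested genes that passed, and do not set these markers apart. Of 14 leukocyte genes CD68 fell (−0.39) and CD14 rose (0.22), with 1 fall and 0 rises adjusted over the list alone (camera adjusted p = 0.546). Of 11 endothelial genes CLDN5 rose (0.26) and 0 fell, with 0 and 0 adjusted over the list alone and 1 and 0 at unadjusted p (camera adjusted p = 0.869). Of 8 adipocyte genes CFD rose (0.22) and LPL fell (−0.18), the same adjusted over the list alone (camera adjusted p = 0.789). Both CD14 (0.15 to 0.27) and CLDN5 (0.21 to 0.33) lost their calls when any array other than suspended replicate 2 was left out, CFD without attached replicate 3 or 4 or suspended replicate 1 (0.17 to 0.25), and LPL without attached replicate 1, 2 or 4 or suspended replicate 3 or 4 (−0.21 to −0.15).

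**Figure D3:**
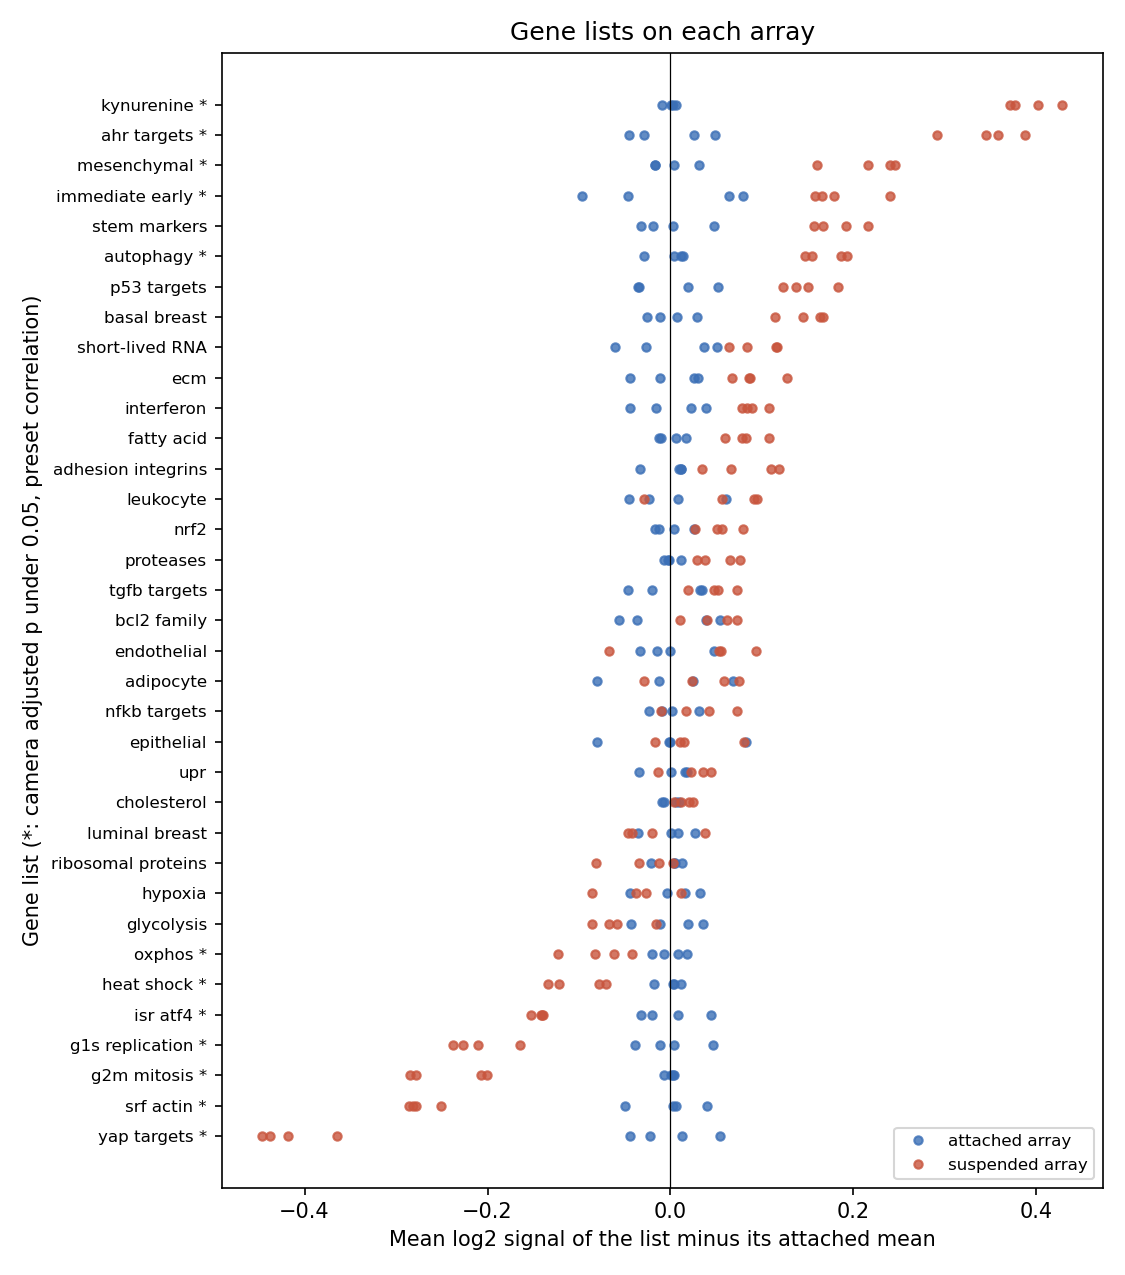
Mean log2 signal of the genes of each of the 35 lists on each of the 8 arrays, after subtracting the mean of the attached arrays; an asterisk marks the 12 lists with a camera adjusted p under 0.05. For each of these 12 the 4 suspended arrays lie on 1 side of the 4 attached arrays.

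Camera with its preset correlation called 12 of the 35 lists, 5 higher and 7 lower, and fry, which asks whether a list's genes move 1 way on balance, called 21. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.184, and 8 had an unadjusted p under 0.05. For 8 lists the median, the mean and camera's direction differed in sign: NF-kB targets, adhesion, proteases, cholesterol synthesis, hypoxia, the BCL2 family, luminal breast genes and short-lived RNAs.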

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

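In 480 groups of 4 arrays, the highest or lowest array was set against the nearest of the other 3: its gap over the range of the group exceeded Dixon's critical value of 0.829 in 27 groups. Chance alone gives about 1 in 20. The values are log2 signals of genes, or means of a gene list relative to the attached arrays, and no explanation was tested for them.

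Attached replicate 1 was lowest for CDH2 (8.89, the others from 8.95), for MMP14 (7.53, the others from 7.69), for ITGB4 (5.81, the others from 5.92) and for SEL1L (7.36, the others from 7.54). It was also lowest in the mean of the adhesion list (−0.033, the others from 0.010). Attached replicate 2 was highest for CD14 (5.57, the others up to 5.48) and for CYP1B1 (6.99, the others up to 6.88). Attached replicate 3 was highest for AADAT (6.73, the others up to 6.60) and lowest for SCD (10.83, the others from 10.90). Attached replicate 4 was lowest for EGFL7 (6.64, the others from 6.70), for GABARAPL1 (7.20, the others from 7.40) and for SEL1L3 (4.92, the others from 5.15).

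Suspended replicate 1 was lowest for ADGRG1 (7.82, the others from 7.97), for CCNA2 (8.73, the others from 8.85) and for FADS2 (10.57, the others from 10.63). It was lowest, too, in the mean of the ATF4 response list (−0.152, the others from −0.141). Suspended replicate 2 was highest for CDKN1A (7.47, the others up to 7.23) and for THY1 (8.43, the others up to 8.37). Suspended replicate 3 was highest for CALD1 (7.70, the others up to 7.46) and for DNAJB9 (5.98, the others up to 5.84), and lowest for DUSP4 (7.52, the others from 7.74). Suspended replicate 4 was highest for ANGPTL4 (7.14, the others up to 6.62), for ITGB4 (6.39, the others up to 6.22) and for LMOD1 (5.85, the others up to 5.58). It was lowest for ATP5F1B (11.60, the others from 11.71), for LEP (4.93, the others from 5.06) and for RPL27 (9.21, the others from 9.42).

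Probe sets outside the gene comparison also changed. Over all 33297 probe sets tested together with limma, 146 of the 12083 without a gene symbol were higher in suspended cells and 350 were lower, and of the 1754 with several symbols 87 were higher and 160 lower. The probe sets without a symbol had a median signal of 5.07, against 6.40 for those with 1 symbol. What they detect is not known here, and any control probe sets among them were not set apart. Their changes are therefore not to be read as changes of unnamed transcripts. The largest changes without a symbol were probe sets 8106403 (log2 difference 1.40, SE 0.06) and 8066266 (1.15, SE 0.06), which rose, and 7894956 (−1.17, SE 0.18) and 7895105 (−1.15, SE 0.08), which fell, each with 4 arrays per group.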

How the results depend on the processing

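Every alternative was chosen before the data were examined. The count of changed genes ran from 2934 (without attached replicate 4) to 4197 (intensity trend) against 3787, and that of genes changed at least 2-fold from 58 (only genes above the median level) to 70 (without suspended replicate 3) against 63. Over all 33297 probe sets, with or without a symbol, 3677 were called and 74 of these probe sets changed at least 2-fold. Of the 3787 calls 0 turned direction with quantile normalization, median centring, array weights or an array left out, and 2 did with the mean of a gene's probe sets; the other refits do not change a gene's difference. For the 204 named genes 2991 of 3221 recomputed values kept direction and side of the threshold, 189 lost it, 30 passed it and 11 turned, 0 of them among called genes. Of the losses 20 came with the replicate block (adjusted p = 0.0521 to 0.114: ANKRD37, ATF3, ATG5, BCL2, CAV1, CD14, CLDN5, DNAJA1, DNAJB1, DNAJB9, FOXA1, HSPH1, KLF6, LPL, NFKB1, NSDHL, PHLDA3, QPRT, SREBF1 and TXNRD1), 13 with median centring (0.0533 to 0.193: ANKRD37, ATF3, CD14, CLDN5, DNAJB9, FOXA1, IDO1, KYAT3, QPRT, RRM2B, SEL1L, STARD4 and TXNRD1), 11 with quantile normalization (0.0574 to 0.192: ANKRD37, ATF3, ATG5, CAV1, CD14, CLDN5, DNAJA1, DNAJB9, FOXA1, HSPH1 and NSDHL), 5 with the intensity trend (0.0521 to 0.0978: BCL2, CD14, DNAJB9, FOXA1 and LPL), 2 with array weights (0.0513 for HSPH1 and 0.0624 for CLDN5), 1 with the mean of a gene's probe sets (0.0672 for AKR1C1) and the rest with an array left out. Replicate numbers did not pair the samples: residuals of same-numbered arrays correlated at 0.04, −0.20, −0.02 and −0.17, and attached replicates 1 to 4 correlated best with suspended replicates 3, 4, 2 and 2. With the replicate number as a block, 3022 genes were called (1505 higher, 1517 lower), 63 at least 2-fold; the immediate-early list lost its call (adjusted p = 0.0653), and the block changed no other list call. What ended or turned a call was not tested, also where fewer genes or arrays were used. Genes of low signal are limited by the lack of a background measure.

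Values for lists are camera's adjusted p. Quantile normalization lost oxidative phosphorylation (0.206) and heat shock (0.0886), and turned the direction of uncalled lists, namely hypoxia (0.972) and, each at 0.977, cholesterol, BCL2 family, epithelial and ribosomal genes. Median centring turned NF-kB targets and the BCL2 family (0.998 each) and gained stem cell markers (0.0439). The uncalled genes ACMSD and KMO turned under both, to −0.003 and −0.006 with quantiles and −0.042 and −0.023 with centring. Keeping genes above the median level gained proteases (0.0398) and stem cell markers (0.0494), lost oxidative phosphorylation (0.255), heat shock (0.0813) and immediate-early genes (0.0588), and turned NF-kB targets (0.979), BCL2 family (0.781), epithelial and basal genes (0.858 each). Above the 25th percentile oxidative phosphorylation (0.0887) and immediate-early genes (0.0679) were lost, and NF-kB targets (0.933), BCL2 family and epithelial genes (0.827 each) turned. Array weights lost oxidative phosphorylation and immediate-early genes (0.0609 each).

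An estimated correlation left 0 of 12 list calls: kynurenine, G1/S, G2/M, YAP, SRF and actin, oxidative phosphorylation, ATF4 and autophagy stood at 0.184, aryl hydrocarbon receptor targets at 0.233, heat shock at 0.249, mesenchymal at 0.200 and immediate-early at 0.746. Fry, which tests another question, called 21 lists: it kept the 12 and added interferon (0.00892), adhesion (0.00979, direction turned to higher), matrix (0.00492), proteases (0.00148), fatty acid (0.000348), p53 (0.00148), basal (0.00018), stem (0.000281) and short-lived RNA genes (0.00892). It also turned the uncalled NF-kB targets (0.396), cholesterol (0.948), BCL2 family (0.377) and luminal genes (0.868).

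With each array left out in turn, 10 or 11 lists were called. Ranges for lists with a changed call or direction were 0.0193 to 0.0622 for kynurenine (lost without suspended replicate 1), 0.0208 to 0.0525 for mesenchymal (lost without suspended replicate 2), 0.0169 to 0.108 for immediate-early and 0.0344 to 0.0933 for oxidative phosphorylation. Uncalled lists that turned ran from 0.775 to 0.989 (BCL2 family), 0.574 to 0.963 (endothelial), 0.680 to 0.954 (epithelial, and hypoxia alike), 0.712 to 0.994 (luminal) and 0.770 to 0.994 (NF-kB). Uncalled genes that turned were AADAT (log2 −0.042 to 0.009), ACMSD (−0.067 to 0.046), AFMID (−0.007 to 0.142), KMO (−0.010 to 0.050) and KYAT1 (−0.074 to 0.021).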

Other observations

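Of the tests in this part, the family tests, their check under other scalings and the snoRNA tests on equal loss and on host genes were chosen after the data had been seen, and groupings by chromosome and by gene type were also looked at. The snoRNA length test and the splits of the arrays were written down before their results.

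In several families of genes that share the first letters of their symbol more members fell than rose in suspended cells. Of 23 nucleoporin genes (NUP), the subunits of the nuclear pore, 17 fell and 0 rose, with a median log2 difference of −0.25. Of the mitochondrial ribosomal proteins, 21 of 48 of the large subunit (MRPL) fell with a median of −0.14, and 10 of 26 of the small subunit (MRPS) with a median of −0.15. Among 31 RNA polymerase subunits (POLR) 15 fell and POLR2A rose (0.17), with a median of −0.20. Of 14 subunits of the mitochondrial inner membrane import machinery (TIMM) 9 fell. The collagens (COL) went the other way: 9 of 44 rose, COL12A1 fell, and the median was 0.10. Of 55 genes with symbols that start with RPL, which include pseudogenes and paralogs beside the cytosolic ribosomal proteins of the large subunit, 7 fell and RPL13P5 rose (0.18), with a median of −0.04. Of 186 families with at least 12 genes, 16 passed an adjusted p of 0.05 by camera with its preset correlation, among them NUP (4.09e-09), MRPL (1.29e-08), MRPS (5.79e-06), POLR (3.06e-06), TIMM (0.000113), COL (0.00602) and RPL (0.0179). With an estimated correlation 0 passed (smallest adjusted p = 0.401), and 12 had an unadjusted p under 0.05. The medians of these 16 families and of 5 small RNA classes, 21 groups in all, kept their sign after quantile normalization (0 flipped). Median centring lowers the difference of every gene alike, so it says nothing of groups that fell; COL (0.10 to 0.05) and the microRNA genes (0.09 to 0.04), the groups with a positive median, kept their sign under it.

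Signals of box C/D snoRNAs, the guides of RNA methylation, were lower in suspended cells: of 115 measured 42 fell and 2 rose, with a median log2 difference of −0.13. The tests were run on the 38 above the median level of all genes, of which 29 fell and 0 rose, with a median of −0.43 (95% bootstrap interval −0.53 to −0.30) and medians of −0.38, −0.33, −0.33 and −0.56 on the 4 suspended arrays. Bootstrap intervals here resample genes, not arrays, so they do not measure the spread between cultures. In the interval of the 38, snoRNAs that share a host gene were resampled as if independent. Across genes, the values argue against an equal loss of all small RNAs from the suspended samples. Over the same signal range 12 spliceosomal snRNAs had a median of −0.10 (−0.18 to 0.01). For the 17 snoRNAs whose 10 host genes were measured, the values argue against lower host transcript levels as the whole explanation. The hosts had a median of −0.03, and the snoRNAs differed from them by a median of −0.26 (−0.54 to −0.20). Of these hosts 2, RABGGTB (−0.23) and TNPO2 (−0.24), did fall. Host signals are transcript levels, so lower transcription or splicing of the hosts was not tested and stays open. Some hosts were very bright, up to 12.9 for HSPA8, and whether a fall reads in full there was not tested. Lower host levels stay open for 20 snoRNAs, with a median of −0.46, whose hosts, such as GAS5 and SNHG1, have no probe set with their symbol alone. A loss of RNA that grows as the RNA gets shorter stays open as a candidate explanation: across the 38 snoRNAs, of 60 to 148 bases, the change rose with length (Spearman rho = 0.34, permutation p = 0.0375, across genes, which are not independent replicates), and 27 box H/ACA snoRNAs, with a median length of 136 bases, had a median of −0.18. Against it, 20 microRNA genes above the median level had a median of 0.09. However, with the labelling uncertain, what the microRNA and the snoRNA probe sets detect is not known. An effect of suspension on the snoRNAs themselves was not tested and stays open as well.

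Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many as 3787 changed genes. The highest of the others gave 0 by limma at adjusted p under 0.05. At unadjusted p the others gave between 221 and 2351, against 5980. Every other split mixes attached and suspended arrays, so the difference between the groups adds to its spread. The 0 therefore says little beyond that the real split ranks first, and with 35 splits a first rank is the strongest result possible. Chance as the source of the counts is not excluded by these splits. The real split also ranked first for genes changed at least 2-fold (63 against 0), with the same limit. It ranked first for gene lists by camera with its preset correlation (12 against 8). With an estimated correlation 0 lists passed in the real split (smallest adjusted p = 0.184), so chance is not excluded for the list calls either. The split that reached 8 lists grouped attached replicates 1, 3 and 4 with suspended replicate 2. It is 1 of 16 that put 3 arrays of a group against 1 and so keep part of the difference between the groups; these gave 4 to 8 lists, while the 18 with 2 attached and 2 suspended arrays on each side gave 0 or 1.

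In both groups the arrays lay at unequal distances from the other group. On the first principal component attached replicates 1 to 4 stood at −13.4, −10.7, −14.1 and −15.2 and suspended replicates 1 to 4 at 15.1, 10.1, 10.9 and 17.5. The change of each array was regressed, through the origin, on the mean change of the others. The genes used were those called in the refit without that array (2934 to 3752 genes). The arrays that chose these genes also gave the mean change, so a slope below 1 need not set an array apart. The slopes were 0.964, 0.901, 1 and 0.986 for the attached and 0.976, 0.888, 0.886 and 1.024 for the suspended replicates. Taken apart, genes that rose and genes that fell gave unlike slopes on some arrays, such as 1.037 and 0.879 for attached replicate 1. On others they were alike, such as 0.987 and 0.984 for attached replicate 4. A test of whether RNA of attached cells accounts for the slopes of suspended replicates 2 and 3 was run, gave no decision and was withdrawn, because it had picked those arrays by their measured position.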
